A study of Mus musculus with 2 samples.

How the data were processed

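H3K4me2 (dimethylation of lysine 4 of histone H3, a mark of promoters and enhancers) was measured by ChIP-seq in lung dissected from mouse embryos at 14.5 days. Per the labels, there were 2 biological replicates of 1 group. Replicate 1 was a pool of 24 embryos and replicate 2 a pool of 34 embryos, male and female together. The labels name a possible control library and the mm10 assembly. The peak caller, the aligner, the read filters and the rule behind the replicated list are not given in the sources used here.

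The authors deposited 4 peak lists: 1 per replicate, 1 called on the alignments of both replicates (pooled peaks) and 1 derived from the pooled list and both replicate lists (replicated peaks), per the deposited file descriptions. Each peak carries a fold enrichment (a ratio), a −log10 p-value and a −log10 q-value that the authors' peak caller gave it. No control sample's own values were deposited with these lists as used here, so the background is contained only in the authors' fold and p-values. The lowest −log10 p was just above 2 in every list, so weak peaks were kept: 149 of the 41426 replicated peaks had a q-value above 0.05. All 41426 replicated peaks were found unchanged in the pooled list of 48522 peaks. Of the replicated peaks, 36797 were touched by peaks of both replicates and 42 by neither. Fold enrichment was used only to describe peaks, to rank them within a list, and to describe the ratio of the replicates without a test, since its scale differs between lists. The number of reads behind each list is unknown, so no interval that needs it was computed, and a longer list in 1 replicate can reflect depth as well as tissue.

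Coordinates are 1-based on mm10, which is the GRCm38 assembly. GENCODE M21 basic annotation and the GRCm38.p6 sequence were used after checking that every peak lay within the chromosome lengths. Peaks on chromosomes 1 to 19, X and Y were analysed. There were 21827 protein-coding genes after 21851 entries were merged by symbol. A gene was called marked when a replicated peak came within 1000 bp of any of its protein-coding transcription start sites (TSSs). Width of the mark was the number of bp covered by peaks within 5000 bp of 1 TSS per gene, the 5′-most TSS of its principal transcripts where the annotation names any and of all its protein-coding transcripts otherwise. Its ceiling is the whole window, which some genes reached. Distal peaks lay more than 2000 bp from every annotated TSS and were assigned by summit to the nearest protein-coding TSS within 100000 bp. CpG content was the observed over expected ratio within 500 bp of the TSS, in 5 bins of equal size.

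A total of 28 gene lists, 13 motif consensuses, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The named genes were, per list, the 2 members with the most bp covered and every unmarked member where there were at most 5; the 10 genes with the most bp covered; the 10 with the most distal peaks; the 5 replicated peaks of highest fold; the 5 strongest peaks found in only 1 replicate, for each replicate; and Nkx2-1, Foxa2, Sox9, Sox2, Fgf10, Tbx4, Tbx5, Foxf1, Shh, Kdr, Wt1 and Sftpc. Other names were chosen after their values were seen, and this is said where they appear. Of the erythroid list, 19 of 20 genes were matched by symbol, since Ahsp was not found.

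Overlap between replicates (at least 50% of a peak covered) and genomic location were compared with 100 circular shifts of the peaks within each chromosome. These allow a smallest p of 0.0099 one-sided and 0.0198 two-sided. Marking was compared between each list and all other genes with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 28 lists. Width (over marked genes) and distal peaks per gene were compared with 100000 random gene sets of the same size, a two-sided permutation test with a smallest p of 2e-05, adjusted likewise. Genes, not animals, are the units of these tests, so they describe this pair of libraries against the annotation and do not measure spread between embryos. Shared genes and linked genes make lists partly dependent. Motif matches per kb in distal peaks were compared with windows of equal length 10000 bp to either side and outside every peak, by an exact sign-flip test over 19 autosomes (smallest p 3.81e-06), adjusted over 13 motifs. The 1 match added to avoid a log of 0 was split by sequence length, since adding it equally had shifted rare motifs towards the shorter side, a correction made after the first values were seen. Scrambled consensuses of the same letters (up to 10 per motif) were counted as a control. No comparison between groups exists in this series. With 2 replicates, values are given per replicate or as mean ± SD (n = 2).

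The alternatives were each replicate's peaks alone, the pooled peaks, peaks with −log10 q of at least 5, other windows and overlaps, and matching on CpG content or on the length of the territory nearest to a gene. Marking at 1 TSS per gene, motif ratios relative to scrambled consensuses, and a count of one-replicate peaks near list genes were added after seeing the data. A second erythroid and a second cardiac list of 30 genes each were also written then, before their own values were seen.

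The tests were tested on simulated data. With 30% of randomly placed peaks copied into a second list, 31.4% were found to overlap, against 2.87% after shifting. Of 200 random lists of 20 genes, 2.5% passed Fisher's test for marking and 3.5% passed the permutation test for width. Lists with width raised 1.5 times were found in 95.5% of cases. For distal peaks, 5% of random lists passed, and 94% of lists with 1.5 peaks added per gene were found. A motif planted to double its density gave a mean log2 ratio of 0.93 over 19 simulated autosomes, and a motif not planted gave 0.07 (exact sign-flip p = 0.112). The simulated sequences had equal base frequencies on both sides. This check therefore does not cover the difference in G and C content between real peaks and windows. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9. The 14 replicated peaks on unplaced scaffolds were left out of all tests because the annotation file used covers chromosomes only.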

Results

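H3K4me2, which marks active and poised promoters and enhancers, was profiled in embryonic lung at 14.5 days, when the airways branch and the distal epithelium has not yet formed alveoli. The series holds 2 libraries of 1 group, each from its own embryo pool. Replicate 1 had 49077 peaks covering 50.9 Mb and replicate 2 had 58546 peaks covering 59.5 Mb. The deposited replicated list holds 41426 peaks covering 56.6 Mb, or 2.08% of the chromosomes, with a median width of 922 bp. Loci are given on mm10. Widths of the mark around a TSS come from the replicated list, with the mean ± SD of the replicates' own values beside them where a spread is given.

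Both lung pools marked largely the same places. At least 50% of the length was covered by the other replicate in 40597 of 49063 replicate 1 peaks (82.7%) and in 35530 of 58532 replicate 2 peaks (60.7%). Shifted peaks gave means of 2.33% and 2.00% (one-sided permutation p = 0.0099, the smallest that 100 shifts can give). Among the 20000 strongest peaks of each replicate the shares were 96.8% and 95.7%. Across 36784 matched peaks, which are not independent replicates, fold enrichment as the authors' peak caller gave it had a Spearman's rho of 0.927 and a Pearson's r of 0.946 on the log2 scale. Median fold enrichment of these peaks was 8.90 in replicate 1 and 12.2 in replicate 2.

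**Figure D1:**
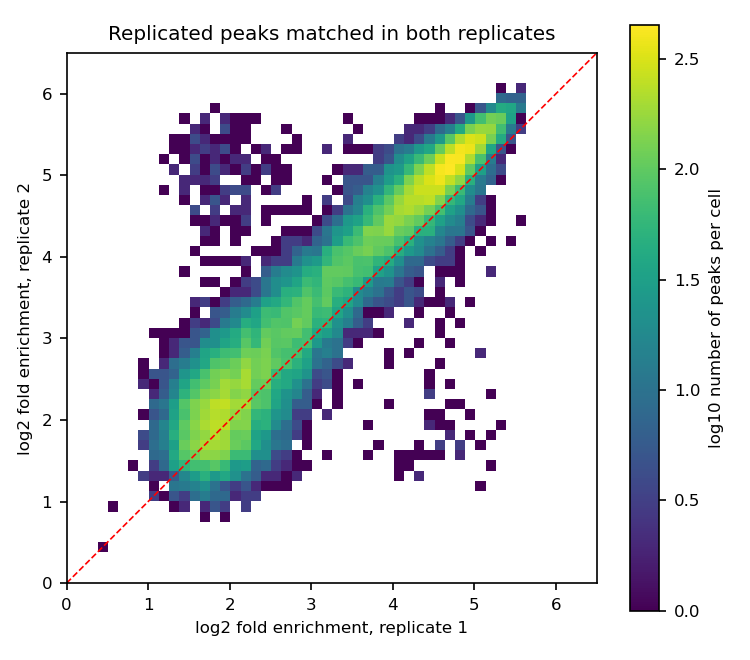
Fold enrichment of matched peaks in replicate 1 (x axis) against replicate 2 (y axis), both on a log2 scale, with colour giving the number of peaks. Most of the 36784 peaks follow a band (rho 0.927) with higher values in replicate 2, and small groups lie off it, strong in either replicate and weak in the other.

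The peak of highest fold enrichment lay at the promoter of the immediate-early gene Egr1 (18:34858987-34863767, fold 62.6), followed by an intronic peak at 6:31215740-31219142 (62.1) whose nearest gene by TSS, Mkln1, starts 182143 bp away. The promoters of Ppargc1b (61.1), Zbtb7c (60.6) and Rasgef1c (60.3) came next. By genomic class, 16712 of 41412 peaks on chromosomes were promoter peaks (40.4%, against 4.51% after shifting; 26.2% against 2.35% with a promoter window of 500 bp), and these held 60.4% of the bp covered. Exons held 5.05% of peaks (shifted 3.12%), introns 32.9% (42.1%) and intergenic sequence 21.7% (50.3%). Each class differed from its shifted share (two-sided permutation p = 0.0198, the smallest possible), but with the 500 bp window introns did not (43.2%, p = 0.891). Promoter peaks had a median width of 1877 bp and a median fold enrichment of 25.7, against 583 bp and 4.28 in introns and 609.5 bp and 4.90 in intergenic sequence.

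Of 21827 protein-coding genes, 14757 (67.6%) had a replicated promoter peak, and 14645 had a promoter peak in both replicates' own lists. Every gene of the lung mesenchyme list (28 of 28, among them Tbx4, Tbx5, Foxf1 and Fgf10), the endothelium list (30 of 30) and the epithelial junction and keratin list (22 of 22) was marked. So were 23 of 24 lung epithelial transcription factors, with Ehf the exception, and 19 of 20 smooth muscle and pericyte genes, with Pln, a calcium pump regulator, the exception. In the alveolar list 15 of 20 were marked, and the surfactant genes Sftpa1 and Sftpd, the lamellar body gene Lamp3, the protease gene Napsa and the lysozyme gene Lyz2 had no promoter peak in either replicate. In the airway list 13 of 22 were marked. In the mesothelium list 11 of 15 were marked, without Gpm6a, Msln, Muc16 and Upk3b.

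Liver had 0 of 20 genes marked (Wilson 95% interval 0 to 16.1%), but 1 of 20 with replicate 1 peaks alone and 3 of 20 with replicate 2 peaks alone. Of these, 1 liver gene had a promoter peak in both replicates' own lists. Olfactory receptors had 8 of 1091 (0.733%, interval 0.372 to 1.44%), macrophage and leukocyte genes 3 of 20, germline and pluripotency genes 5 of 18 (3 with replicate 1 peaks alone), erythroid genes 6 of 19, skeletal muscle genes 8 of 20 and cardiac genes 11 of 22. Transcription factors of brain (20 of 22, without Neurod6 and Otx2) and of gut and pancreas (14 of 16, without Isx and Nkx6-3) carried promoter peaks too, and neural crest, glia and airway neuron genes had 16 of 20 marked, without Dbh, Phox2b, Plp1 and S100b. All genes of the FGF (18), Hedgehog (13), WNT (31), BMP and TGF-beta (27), Notch (16) and housekeeping (26) lists were marked, and 17 of 18 retinoic acid genes, without Cyp26c1.

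By Fisher's exact test (two-sided, adjusted over 28 lists), 14 lists were marked more often and 6 less often than other genes. Adjusted p-values were 7.3e-05 for endothelium, 1.0e-04 for mesenchyme, 9.5e-04 for epithelial junction genes, 0.00381 for epithelial transcription factors, 0.0130 for smooth muscle, 2.2e-09 for liver, 1.7e-05 for macrophages, 0.00174 for germline and 0.0211 for skeletal muscle. HoxA and HoxB groups 1 to 6 had 0.0201, while HoxC and HoxD groups 1 to 6 (6 of 6, exact 0.227) and Hox groups 9 to 13 (13 of 16, 0.345) did not pass. The pathway lists ranged from 5.3e-05 (WNT) to 0.0207 (Hedgehog), housekeeping had 2.2e-04, and brain 0.0289. Airway (0.402), alveolar (0.658), mesothelium (0.786), neural crest (0.380), cardiac (0.141) and gut (0.141) lists did not pass. CpG-rich promoters were marked in nearly every gene (99.4% in the richest of 5 bins, 8.52% in the poorest). When genes were compared within bins of CpG content, 4 lists stayed higher (endothelium 4.1e-07, mesenchyme 5.2e-05, smooth muscle 8.3e-04, epithelial junction 0.0205) and 3 lower (liver 0.00128, germline 1.9e-08, olfactory receptors 4.8e-64). The calls of the epithelial transcription factors (0.521), the housekeeping list, HoxA and HoxB groups 1 to 6 (0.131), skeletal muscle, macrophages and every pathway list ended, and the direction turned for erythroid (31.6% against 24.3% of matched genes) and brain (90.9% against 93.1%). Among lists that had not passed, it turned for cardiac genes (50% against 46.5%, 0.830) and Hox groups 9 to 13 (81.3% against 95.6%, 0.0735). The share expected from matched genes was already 89.9% for epithelial transcription factors, 94.7% for housekeeping and 96.8% for WNT. Among the pathway lists it was lowest for retinoic acid (75.9%) and Notch (88.3%). Near this ceiling a list had little room to pass as higher. An ended call there does not show that CpG content explains the marking. With replicate 1 peaks alone, the erythroid call (52.6% marked, Fisher's exact adjusted p = 0.292) and the retinoic acid call (88.9%, 0.110) ended. Brain and retinoic acid calls also ended with a 500 bp window (0.223 and 0.0667), with which cardiac genes became less marked (40.9%, 0.0186), and with marking at 1 TSS per gene (81.8%, 0.233, and 83.3%, 0.197, chosen after seeing the data).

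**Figure D2:**
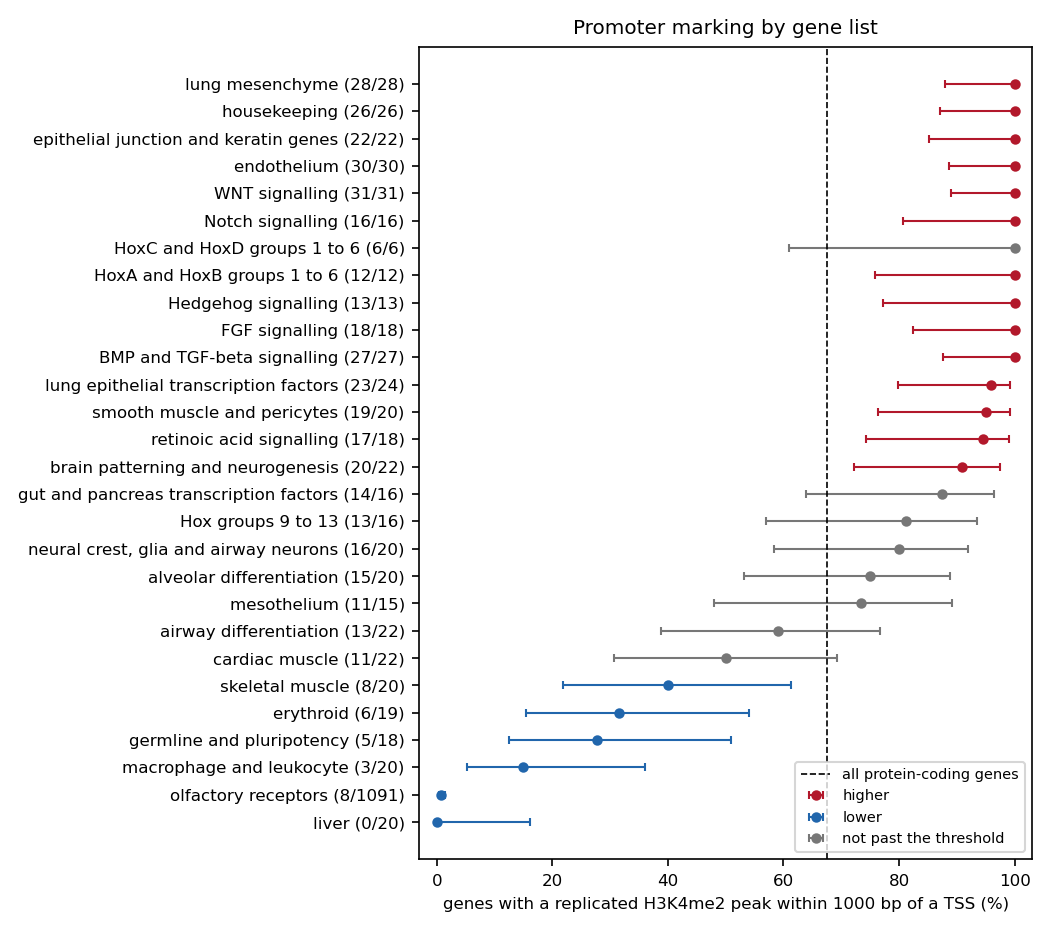
Percent of genes with a replicated promoter peak (x axis) in each gene list (y axis), with Wilson 95% intervals. Endothelium, mesenchyme and the FGF, Hedgehog, WNT, BMP and TGF-beta and Notch lists reach 100% and liver 0%, against 67.6% of all genes.

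The mark was broad at the regulators of lung development. It filled the whole 10001 bp window around the TSSs of Nfib (4:82290173-82705750), Foxf1 (8:121084386-121088144), Tbx5 (5:119832668-119885219) and Ptch1 in the replicated list and in each replicate. Nkx2-1, the lung lineage factor (12:56531958-56536908), had 7326 bp covered (6819 ± 225 bp, n = 2), Foxa2 7557 bp (7448.5 ± 136), the distal tip factor Sox9 7217 bp (7177.5 ± 349) and the proximal factor Sox2 5817 bp (4834 ± 574). In mesenchyme, Fgf10, the growth factor that drives budding, had 6440 bp (6042 ± 260), Tbx4 5797 bp (5763 ± 109), and Shh, whose product signals from epithelium to mesenchyme, 5940 bp (6004 ± 148). The surfactant gene Sftpc (14:70520949-70524081) had 5557 bp (5378 ± 566), while the surfactant genes Sftpa1 and Sftpd were unmarked. The territory nearest to Sftpc spans only 5.32 kb, and its promoter peak (14:70517433-70523939) ran past the 3′ end of the gene. The width at Sftpc may therefore belong partly to neighbouring genes. The endothelial receptor gene Kdr had 4868 bp (4429.5 ± 532). Wt1, a mesothelial factor, differed between replicates, with 2341 bp in replicate 1 and 5894 bp in replicate 2.

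Marked epithelial transcription factors averaged 6713 bp (6536 ± 236 bp over replicates, n = 2), mesenchyme genes 6164 bp (6009 ± 371) and HoxA and HoxB groups 1 to 6 8376 bp (8250.46 ± 299), against 2915 bp in other marked genes for the first of these. FGF genes averaged 5482 bp (5330.0 ± 422), Hedgehog genes 5468 bp (5403 ± 200.4), Notch genes 5489.6 bp (5236 ± 587), BMP and TGF-beta genes 5085 bp (4978 ± 307), WNT genes 4819 bp (4690.2 ± 357) and endothelial genes 4406 bp (4173 ± 527). These 9 lists all had a permutation adjusted p of 5.4e-05, the smallest the resampling can give. Housekeeping (3823 bp, 0.00845), smooth muscle (3818 bp, 0.0270) and epithelial junction genes (3719 bp, 0.0325) were also broader, which makes 12 lists. The 5 narrower lists were brain factors (1863 bp, 9.9e-04), skeletal muscle (1737.5 bp, 0.0219), Hox groups 9 to 13 (1519 bp, 4.4e-04), germline (1285 bp, 0.00814) and olfactory receptors (622 bp, 5.4e-05). Other lists did not pass: retinoic acid (3741 bp, 0.0508), erythroid (3660.2 bp, 0.322), mesothelium (3399.8 bp, 0.344), gut (3091 bp, 0.726), alveolar (3031 bp, 0.778), macrophage (2815 bp, 0.978), airway (2737 bp, 0.737), cardiac (2445 bp, 0.344), neural crest (2404 bp, 0.219) and HoxC and HoxD groups 1 to 6 (2289 bp, 0.344). The macrophage mean rests on 3 genes. It was 3159.5 bp with replicate 1 peaks alone and 1700 bp with replicate 2 peaks alone, over 4 genes each. With replicate 1 peaks alone, epithelial junction (0.0525), smooth muscle (0.302) and germline (0.144) calls ended, and cardiac (0.00667) and HoxC and HoxD (0.0340) became narrower. The smooth muscle call also ended with −log10 q of at least 5 (0.0567), and smooth muscle (0.419) and endothelium (0.0955) in a 2500 bp window. In a 10000 bp window the calls of brain (0.168), skeletal muscle, germline, epithelial junction and smooth muscle (0.222 each) and Hox 9 to 13 (0.240) ended, and matching on CpG content ended that of skeletal muscle (0.395) and brought in retinoic acid (0.0189). Retinoic acid genes also passed as broader with replicate 2 peaks alone (0.0305), with pooled peaks (0.0414), with −log10 q of at least 5 (0.0466) and in the 10000 bp window (0.0150). Cardiac (0.00990) and neural crest genes (0.0230) became narrower in the 2500 bp window, and the 3 liver genes marked with replicate 2 peaks alone were narrower than others (397 bp, permutation 3.1e-04).

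**Figure D3:**
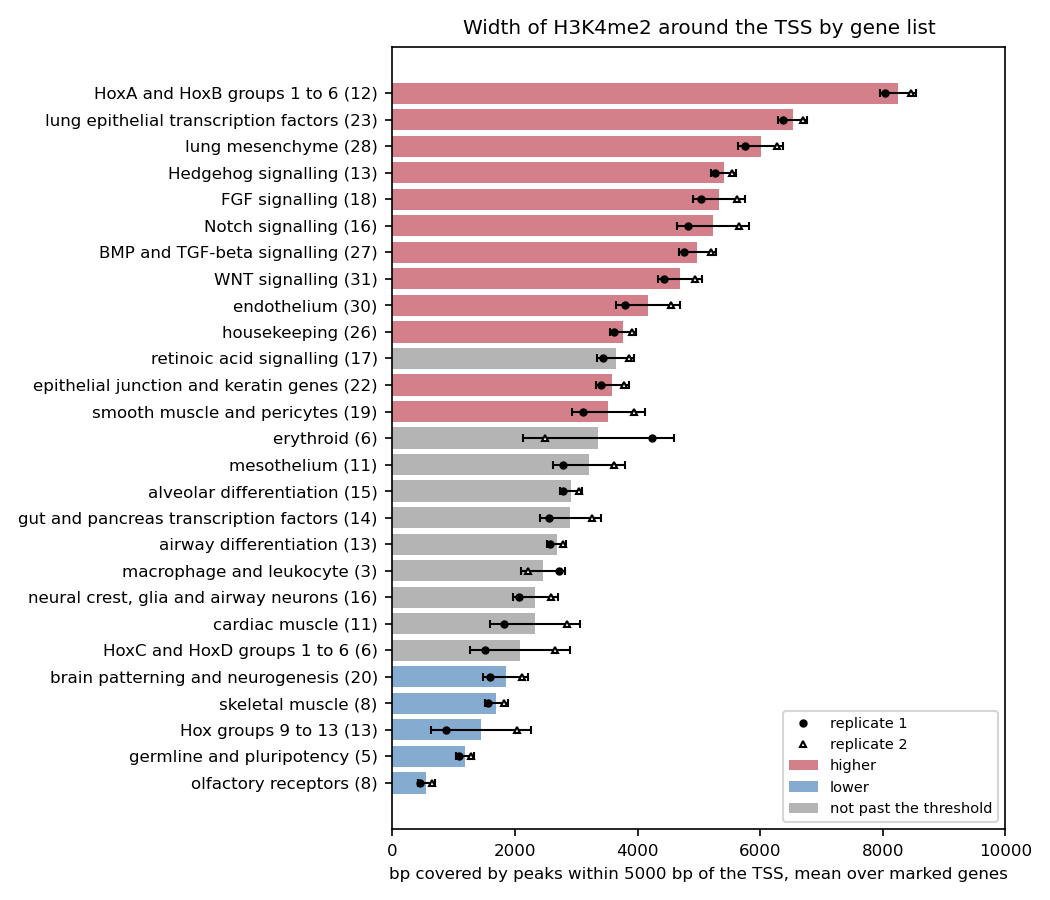
Mean bp covered by H3K4me2 peaks within 5000 bp of the TSS (x axis) for marked genes of each list (y axis). Bars give the mean of both replicates' own values ± SD (n = 2), and points give each replicate. HoxA and HoxB groups 1 to 6 stand at 8250 bp and olfactory receptors at 553 bp.

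Among single genes of the lists, the broadest after those above were the epithelial Irx2 (9810 bp), Cldn6 (9357 bp) and Esrp1 (5587 bp), the endothelial Nr2f2 (10001 bp) and Ephb4 (8663 bp), the mesothelial Igfbp5 (6930 bp) and Podxl (5491 bp), and the smooth muscle Ednra (6667 bp) and Heyl (5674 bp). Airway genes were led by Gfi1 (5663 bp) and Myb (3999 bp), alveolar genes by Sftpc and the caveolin gene Cav1 (5329 bp), and glial and nerve genes by Erbb3 (5771 bp) and Ednrb (5353 bp). In the pathways the broadest were the FGF target Dusp6 (7955 bp) and Fgf9 (7573 bp), the Hedgehog receptor gene Ptch1 and Gli3 (7345 bp), Lef1 (7416 bp) and Fzd7 (7344 bp) for WNT, Id2 (9531 bp) and Id3 (8576 bp) for BMP, Hes1 (8916 bp) and Dll4 (8676 bp) for Notch, Rara (7648 bp) and Rxrb (6564 bp) for retinoic acid, and Actb (6505 bp) and Chmp2a (5679 bp) for housekeeping. In the lists of other cells and organs the broadest mark lay at Tal1 (6693 bp), which like Prox1 is also in the endothelium list, Nfe2 (6644 bp, with 7308 bp in replicate 1 and 3418 bp in replicate 2), Ikzf1 (3381 bp), Gata4 (8235 bp), Prox1 (7500 bp), Mylpf (4790 bp), Actn3 (2678 bp), Tbx20 (3855 bp), Irx4 (3095 bp), Emx1 (3792 bp), Eomes (2891 bp), Tdrd1 (2579 bp), Utf1 (1185 bp), Olfr56 (1256 bp) and Olfr94 (1179 bp). Cd68 (4786 bp), Apoa2 (2274 bp) and Apoa1 (1416 bp) had peaks in the window but no replicated peak within 1000 bp of a TSS. Over all genes the window was filled, with ties taken by name, at Bahcc1, Foxf1, Hoxa2, Hoxa5, Hoxa6, Hoxb3, Hoxb4, Hoxb5, Kdm6b and Meis2.

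The HoxA and HoxB clusters carried a broad mark over most of their anterior and middle genes. Their groups 7 and 8, which the comparison below leaves out, had 7161 bp (Hoxa7), 6219 bp (Hoxb7) and 6308 bp (Hoxb8). Each was broader than Hoxb6 (4995 bp). In HoxD the anterior Hoxd1 (1324 bp) was no broader than the posterior Hoxd13 (1763 bp). The widest peak of all covered 49288 bp of the HoxB cluster (11:96298244-96347531), and peaks of 26814 bp at Hoxa4 (6:52187883-52214696) and 26019 bp at Hoxa1 followed. HoxA and HoxB groups 1 to 6 had 8376 ± 2625 bp covered (SD over 12 genes) and groups 9 to 13 of all clusters 1277 ± 840 bp (16 genes), a difference of 7099 bp (two-sided permutation p = 2e-05, the smallest possible). With 1 replicate alone the difference was 7293 bp (replicate 1) and 6710.15 bp (replicate 2), while the mean of groups 9 to 13 moved from 745 bp (replicate 1) to 1752 bp (replicate 2). Hoxb1 was the narrowest of HoxA and HoxB groups 1 to 6 (1589.5 ± 67.2 bp, n = 2). Hoxc5 (4424 bp) and Hoxc4 (3603 bp) led HoxC and HoxD groups 1 to 6, which averaged 2289 bp. HoxC and HoxD genes entered the comparison only through groups 9 to 13, so its difference and p do not separate cluster from group. Hoxa9 (3034 bp) and Hoxb9 (2555 bp) led the posterior genes, of which Hoxc11, Hoxc12 and Hoxd12 had no replicated promoter peak. Replicates differed at posterior genes, with 934 and 4556 bp at Hoxa9 and 295 and 3538 bp at Hoxa11. Neighbouring genes share peaks, so these genes are not independent. Hoxb1, Hoxb6, Hoxa7, Hoxb7, Hoxb8, Hoxd1, Hoxd13, Hoxa11 and the widest peaks were chosen after their values were seen.

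**Figure D4:**
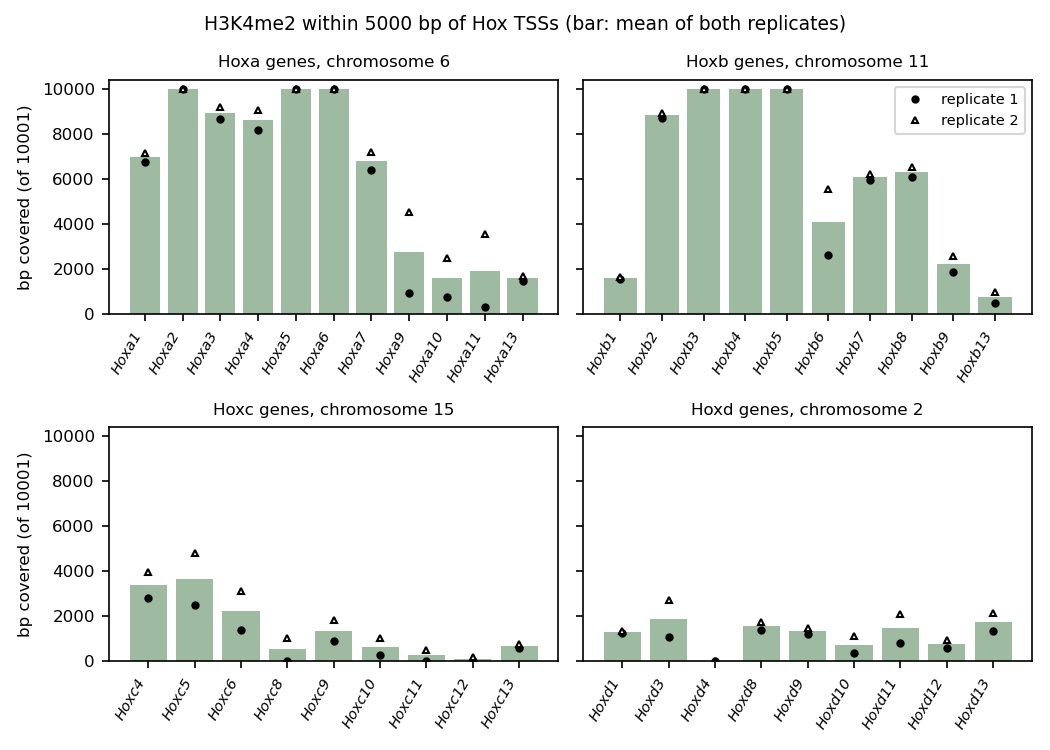
Bp covered by H3K4me2 peaks within 5000 bp of the TSS (y axis) for each Hox gene, by cluster and group. Bars give the mean of both replicates' own values and points give each replicate. Bars of HoxA and HoxB groups 2 to 6 lie between 4090.5 bp (Hoxb6) and the ceiling of 10001 bp. Groups 9 to 13 average 745 bp in replicate 1 and 1752 bp in replicate 2.

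Distal peaks, the candidate enhancers, were most frequent around signalling and lineage genes. Of 20624 distal peaks, 16854 were assigned to 7385 genes, a mean of 0.772 per gene. Zfhx3 had the most (25), followed by Smad7 and Tns1 (22 each), Bach2, Gse1 and Mecom (21 each), Bcor (20), and Cstad, Foxp1 and Ncor2 (19 each). Nfib had 18, Hes1 13, Foxa2 11, Tbx5 10, Dusp6 and Dll4 9 each, Sox9 7, Tbx4 6, Foxf1 and Kdr 5 each, Nkx2-1 4, Fgf10 3, Sox2 and Wt1 2 each, Sftpc 1 and Shh 0. FGF genes averaged 4.56 distal peaks, Notch 4.31, mesenchyme 4, Hedgehog 3.77, epithelial transcription factors 3.75, BMP and TGF-beta 3.63, endothelium 3.43 and WNT 3.42, against 0.77 elsewhere (adjusted permutation p between 8.0e-05, the smallest possible, and 5.6e-04). Brain (2.27, 0.00734), gut (2.13, 0.0353) and smooth muscle (2.05, 0.0257) genes also had more, and olfactory receptors fewer (0.0202). Matching on the length of the territory nearest to a gene raised the comparison mean, to between 1.02 (Notch) and 1.52 (epithelial transcription factors), kept the first 8 calls (0.0146 at most) and ended those of brain (0.0974), gut (0.154) and smooth muscle (0.0664). The brain call also ended with replicate 1 peaks alone (2.18, adjusted permutation p = 0.0604), and those of smooth muscle (0.0726) and gut (0.147) beyond 5000 bp. With replicate 2 peaks alone, means rose by more than 1.5 times in several of these lists, to 7.15 in Hedgehog, 6.94 in FGF, 5.97 in endothelium and 4.31 in gut genes, while the mean of genes outside the Hedgehog list rose from 0.77 to 1.24. Other lists did not pass, from 0.2 peaks per gene in liver to 1.44 in retinoic acid genes. Erythroid genes had 1.42 in replicate 1 and 0.684 in replicate 2.

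Motif matches in distal peaks were compared with windows beside them in 19941 peaks. CTCF was 4.94 times as dense in peaks (mean log2 ratio 2.27 ± 0.52 over 19 autosomes, higher in 19), ETS 2.97 times (1.59 ± 0.61, 19), TEAD 1.36 times (0.45 ± 0.11, 19), MEF2 1.44 times (0.52 ± 0.45, 17) and NF1, the site of Nfib, 4.66 times (1.39 ± 1.09, 16) from 37 and 14 matches. Adjusted two-sided exact sign-flip p-values were 1.2e-05 for the first 3, the smallest possible, 3.5e-04 for MEF2 and 1.6e-04 for NF1. The E-box CATATG was less dense (0.485 times, log2 -1.03 ± 0.17, higher in 0 autosomes, 1.2e-05), as were SOX (0.824 times, -0.33 ± 0.41, 5, 0.00140) and AP1 (0.929 times, -0.11 ± 0.17, 7, 0.0242). FOX (1.04 times, 0.257), NKX2 (1.03, 0.295), GATA (1.05, 0.305), HNF4 (0.983, 0.867) and REST (4 and 2 matches, 0.295) did not pass. Peaks were richer in G and C than the windows (50.7% against 45.2%). The MEF2 call ended with replicate 1 peaks alone (adjusted sign-flip permutation p = 0.0563) and with windows 5000 bp away (0.0870), where GATA passed (1.11 times, 0.0289). The AP1 call ended with either replicate alone (0.319 and 0.496), with pooled peaks (0.112) and with windows 5000 bp away (0.0968). Relative to scrambled consensuses, a comparison chosen after seeing the data, the mean log2 ratios of CTCF (1.39) and ETS (0.63) shrank and that of NF1 was 1.44, FOX (1.49 times, 1.2e-05) and GATA (1.22 times, 1.4e-04) became denser in peaks, AP1 turned to 1.11 times (0.00293) and SOX to 1.07 times (0.434).

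Peaks found in 1 replicate with no base covered in the other numbered 6401 of 49063 in replicate 1 and 18797 of 58532 in replicate 2. The strongest in replicate 1 lay in introns of Afg3l2 (fold 9.17), March2 (7.93), Fech (7.39 and 7.10), which encodes the last enzyme of heme synthesis, and Bola3 (7.37). In replicate 2 they lay near Nipbl (9.66), Kctd1 (9.31) and Foxi3 (9.31) and at the promoters of Ogn (9.11) and Hoxc8 (8.83). Of 19 erythroid genes, 6 had a promoter peak in replicate 1 only (Epb42, Ermap, Gata1, Slc4a1, Spta1 and Trim10) and 0 in replicate 2 only. Of 22 cardiac genes, 2 had one in replicate 1 only and 6 in replicate 2 only. The other names here were chosen after their values were seen. Comparing fold enrichment at shared promoters, the median log2 ratio of replicate 2 over replicate 1 was 0.42 over 14645 genes. With 1 library on each side this has no test. Of 24 lists, 4 lay outside the central 95% of random lists, where 1.2 would by chance: mesenchyme (99.4th percentile) and brain (98.6) towards replicate 2, and housekeeping (0.97) and BMP and TGF-beta (2.48) towards replicate 1. By bp covered in place of fold enrichment, 13 lists did, BMP and TGF-beta turned towards replicate 2 (99.8th percentile), and housekeeping lay inside (65.5).

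**Figure D5:**
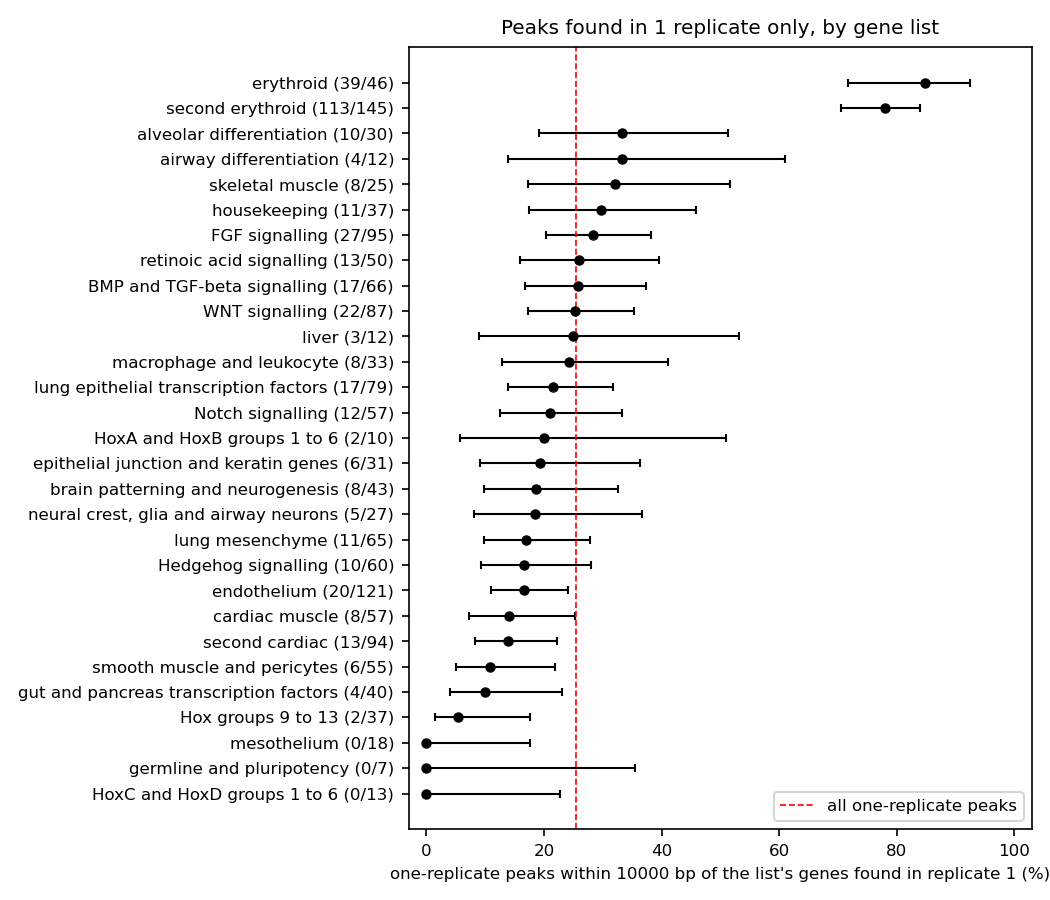
Percent of peaks found in only 1 replicate that came from replicate 1 (x axis), for peaks near genes of each list (y axis), with Wilson 95% intervals. The erythroid list stands at 84.8% and peaks elsewhere near 25.4%.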

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

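No test here was chosen after the result was seen except the description of the scaffold peaks, and no biological explanation was tested, since the series has a single group. The replicated list held 14 peaks on scaffolds not placed in the assembly, which the comparisons left out. Of these, 7 lay on an unlocalized scaffold of chromosome X, and fold enrichment ran from 3.83 to 13.7. The annotation file used here does not cover these scaffolds, so the genes they belong to are not named.

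The pooled list held 7096 peaks that the replicated list did not. Apart from the exclusion of every peak from the motif windows, these peaks entered only the comparisons run on the pooled list. Their median fold enrichment was 2.82, against 7.99 in the replicated peaks. Using the pooled list in place of the replicated one changed 1 call in the analyses by gene list and by genomic class, for width, and 1 among the motifs.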

How the results depend on the processing

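The ratios relative to scrambled consensuses, marking at a single TSS per gene and the count of one-replicate peaks near list genes were chosen only after the results were seen; the other alternatives were planned. Of 1206 comparisons of a result with an alternative, 1056 kept their call in its direction, stayed without a call or stayed within the spread, 89 moved, 43 lost their call, 14 gained one and 4 reversed. Among single genes, lists and motifs, 965 of 1107 comparisons stayed the same, 82 moved, 42 lost their call, 14 gained one and 4 reversed. Overlap of the replicates, their agreement in fold enrichment and the Hox difference kept their direction under every alternative run on them. The share of intronic peaks was 43.2% with a promoter window of 500 bp and no longer differed from shifted peaks, and that of promoter peaks was 26.2%, still above shifted peaks. Each peak was classed once by its summit, promoters first, so the narrower window moved promoter peaks into the other classes. Promoter peaks fell from 16712 to 10856 and intronic peaks rose from 13608 to 17901. For the results that follow, the cause was not tested. Matching on CpG content left 4 lists marked more often and 3 less often. In a 10000 bp window, 1 list was narrower, and beyond 5000 bp from every TSS 2 lists had fewer distal peaks, Hox groups 9 to 13 being added with 0 peaks (permutation adjusted p = 0.0341). By bp covered, 13 lists differed between replicates beyond the central 95%. Relative to scrambled consensuses, 8 motifs were denser in peaks and 1 less dense. Of the results past the threshold, those that reversed were the erythroid (31.6%) and brain (90.9%) lists, whose marked shares changed sides of their expectation when matched on CpG content, and AP1 (1.11 times) and SOX (1.07 times) relative to scrambled consensuses. Widths and counts of peaks rest on the authors' calls, and without read counts their dependence on depth could not be measured.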

Other observations

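The gene families, the count of one-replicate peaks near list genes, and the tests on brain and gut factors and on liver cells were chosen only after the results were seen; the other tests below were written before the values they measure. Families with related names differed in how they carried the mark. They were compared with all other genes, without matching on CpG content or territory length. Such matching ended many calls among the gene lists, so the family values may partly reflect both. Several Id, Irx and Smad genes also belong to those lists. Id genes, which encode inhibitors of differentiation, had 7129 bp covered around the TSS over 4 genes (SD 2352, permutation adjusted p = 9.3e-05), and the 6 Irx genes had 7011 bp (SD 3338, permutation adjusted p = 9.3e-05). The 8 Smad genes, which encode signal mediators, averaged 7.13 distal peaks against 0.77 elsewhere (permutation adjusted p = 1.1e-04). All 19 Sox genes and 38 of 44 Fox genes were marked, with 4043 and 4215 bp. Pax genes, which pattern other organs, were narrow where marked (1476 bp over 7 genes, permutation adjusted p = 0.0047) yet averaged 2.89 distal peaks (permutation adjusted p = 0.0211).

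Histone genes were marked in 61 of 67 cases and broad (5423 bp, SD 1790.5, permutation adjusted p = 9.3e-05). They had few distal peaks (0.299 against 0.774 elsewhere, permutation adjusted p = 0.0085). Neighbouring TSSs inside the window and territory length were not accounted for, so both values are not separated from gene spacing. Zinc finger genes named Zfp were marked more often than others (345 of 394, Fisher's exact adjusted p = 2.9e-19) but narrower (2623 bp, permutation adjusted p = 6.4e-04). All 78 mitochondrial ribosomal protein genes were marked, at an unremarkable width (2709 bp, permutation adjusted p = 0.262). Clustered protocadherins (20 of 56), interleukin and receptor genes (38 of 82), cytochrome P450 genes (25 of 100), keratins (8 of 53), keratin-associated proteins (1 of 57), vomeronasal receptors (1 of 330) and beta-defensins (0 of 42) were marked less often than others. Fisher's exact adjusted p ran from 3.2e-160 (vomeronasal receptors) to 1.9e-04 (interleukin and receptor genes). Without matching on CpG content, low CpG content is not separated from the family.

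Peaks found in only 1 replicate were weak: with the peaks of each replicate ranked by fold enrichment into 4 equal parts, 0% of the top part lay in 1 replicate only, while in the lowest part 35.1% of replicate 1 peaks and 73.8% of replicate 2 peaks did. In the next part above the lowest the shares were 16.5% and 49.8%. Weak peaks near the calling threshold may therefore account for many of them. The strongest were not near it, with a −log10 q of 21.1 in replicate 1 and 24.4 in replicate 2. The top part began at fold 18.0 and 19.9, far above the medians of intronic peaks (3.84 and 3.71). It therefore says little about distal peaks. One-replicate peaks were not spread evenly over genes. Promoters with a peak in 1 replicate only were more frequent in the cardiac (exact adjusted p = 1.9e-08), erythroid (3.3e-06) and germline (0.0161) lists than elsewhere. A different mix of cells in the embryo pools therefore stays open beside the threshold. Depth is unknown and each side is a single library, so pool, depth and library preparation are not separated.

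More erythroid cells in the pool of replicate 1 are a candidate explanation for part of this. Near erythroid genes 84.8% of one-replicate peaks (39 peaks against 7) came from replicate 1, against 25.3% elsewhere, and near a second erythroid list of 30 genes 77.9% did (113 peaks against 32, more from replicate 1 at 23 genes and from replicate 2 at 3, Fisher's exact p = 3.9e-40). Peaks of 1 gene are not independent, so this p is too small. GATA motifs were 1.40 times as dense in distal peaks of replicate 1 only as in those of replicate 2 only (log2 0.45 ± 0.47, higher in 16 of 19 autosomes, exact sign-flip p = 7.9e-04, adjusted 0.0103). The globin genes Hba-a1, Hba-a2, Hba-x, Hbb-bt, Hbb-bs, Hbb-bh1 and Hbb-y and the heme gene Alas2 had no promoter peak in either replicate. These names were chosen after their values were seen. Peaks missing from both replicates cannot show which pool held more erythroid cells, and the read filters are unknown. As a limit, Tal1 of the list is also an endothelial gene.

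More cardiac cells in the pool of replicate 2 could be proposed likewise, on weaker grounds. Near a second cardiac list 13.8% of one-replicate peaks came from replicate 1, against 25.4% elsewhere (13 against 81, more from replicate 2 at 20 of 30 genes, Fisher's exact p = 0.00867). That count of genes is no excess, since the WNT list, with 25.3% from replicate 1, leaned to replicate 2 at 20 of 31 genes. Peaks of 1 gene are not independent here either, so this p is too small. MEF2 motifs were 0.747 times as dense in distal peaks of replicate 1 only (exact sign-flip p = 0.0265, adjusted 0.115), while TEAD motifs, which are not particular to heart, passed in the same direction (0.876 times, higher in 4 of 19 autosomes, adjusted 0.0349). The first cardiac list (14.0%, Fisher's exact adjusted p = 0.164) did not pass, and smooth muscle (10.9%), gut (10%), mesothelium (0 of 18) and Hox 9 to 13 (5.41%, adjusted p = 0.0498) leaned the same way, so the lean is not particular to heart genes.

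Promoters of genes from other organs carried replicated peaks in 58 of 118 cases, fewer than the 73.9 (66 to 82) of random genes with the same CpG content (exact p = 3.0e-05). A bound on either side had been set, but a deficit leaves no marking for CpG content to fail to explain, so this test decides nothing about CpG-rich promoters. For brain and gut transcription factors alone, 34 of 38 were marked where 33.9 (31 to 36) were drawn, so CpG-rich promoters that carry the mark in any tissue may suffice there. Cells of other organs cannot be told apart from background: CpG-poor cardiac, skeletal muscle and liver genes were marked in 18.9% of cases (10.6 to 31.4%), an interval that holds the 24.4% of all CpG-poor genes. Cardiac (5 of 16, 31.25%) and skeletal muscle genes (5 of 17, 29.4%) stood above that share and liver genes below. Without olfactory receptors the share of CpG-poor genes was 27.8%, and these counts are too small to show an excess. Liver cells in the dissected lung stay open too: 0% of CpG-poor liver genes were marked (upper limit 16.1%), and 5% with replicate 1 peaks alone (upper limit 23.6%, below the 24.1% of all CpG-poor genes), but 15% with replicate 2 peaks alone (upper limit 36.0%, above the 25.9% of all CpG-poor genes).

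Broad marking at developmental regulators was tested on the epithelial factor, mesenchyme, brain and gut lists together, although brain genes alone were narrower than others and gut genes not broader (3091 bp, permutation adjusted p = 0.726), so the pattern is that of the epithelial factor and mesenchyme lists. Within bins of promoter CpG content, their 84 marked genes exceeded others by 1946 bp, against 1906 bp without matching (permutation p = 2e-05 for both, the smallest possible). Among the 79 genes of these with no other gene's TSS within 10000 bp, the excess was 2221 bp. Neither CpG content within 500 bp of the TSS, as binned here, nor neighbouring TSSs could thus be the whole account. CpG content over the rest of the window in which width was measured was not matched, so CpG content as such is not excluded. Depth and the peak caller's joining of neighbouring peaks were not tested, and the pattern stays a hypothesis because it was found and tested on the same pair of libraries.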
